A study of Rattus norvegicus with 36 samples.

How the data were processed

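The series measured transcript levels in the liver of male Sprague Dawley rats given hexabromocyclododecane (HBCD), a brominated flame retardant, by oral gavage in corn oil. Per the labels' protocols, dosing ran for 5 consecutive days from an age of 7 weeks, in a volume of 5 ml/kg. Left liver lobe taken 1 day after the last dose gave the RNA. The 36 arrays fell into 6 groups of 6: corn oil vehicle, and HBCD at 641, 64.1, 6.41, 0.641 and 0.06 mg/kg. Groups and replicate numbers came from the sample labels. The labels number the replicates without stating that each array came from a separate rat, so p-values measure the spread between these samples, which may be technical.

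The deposited values were log2 expression values per probe set, made by the authors with RMA and the affy package per the submitters' processing notes. RMA corrects the background, normalizes between arrays and summarises the probes of a probe set. The versions and settings were not given in the sources used here. The log2 scale was read from the values, which ran from 1.526 to 14.59, and the array medians lay between 4.829 and 4.899. No further normalization was applied. The files held no detection calls, so probe sets near the background were not separated from the rest, and the number of arrays limits the precision. No pair of arrays held identical values, and arrays of a group correlated at 0.991 to 0.997 across probe sets, so all were used as separate samples.

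Of 31099 probe sets, the 57 control probe sets were left out and 31042 were tested. In the platform annotation used here, 20826 tested probe sets had 1 gene symbol, 436 had several and 9780 had none. Symbols were brought up to date through a gene table of assembly GRCr8, with 20758 matched by gene ID, 2 by accession and 66 kept as they stood. Probe sets with several symbols were not assigned to a gene. Of the 14217 distinct symbols, each was represented by the probe set with the highest mean over all arrays. No coordinates are given, because the sources used here name no genome build for the array values.

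The series design text names R/maanova with a false discovery rate of 5%. That package was not used here, and limma 3.58.1 in R 4.3.3 fitted the same model, with group as the single factor over all 36 arrays. Contrasts compared each dose with vehicle and 641 with 64.1 mg/kg. A linear contrast over the dose ranks gave the slope per dose step, and a moderated F test covered all 5 dose contrasts. Tests were two-sided, with Benjamini-Hochberg adjustment within each contrast and calls at an adjusted p under 0.05. Fold changes carry 95% confidence intervals from the moderated fit, and SE denotes its standard error. Adjusted p-values without another name are from limma.

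Before the data were examined, 28 gene lists were fixed, 19 for functions of the liver and 9 for markers of other cell types or of exocrine pancreas. Each was tested at each dose with camera from limma at a preset inter-gene correlation of 0.01, adjusted over all 140 tests. Camera with an estimated correlation and fry were run beside it. The named genes followed a rule fixed at the same time. At 64.1 and 641 mg/kg it took up to 10 called genes with the largest rise and 10 with the largest fall in which all 6 treated arrays lay on the same side of the vehicle mean, and at lower doses up to 5 each. At 641 mg/kg it took up to 2 called members per list and direction, or the member with the smallest p where none was called. It took 13 genes at every dose, of which Cyp2b1, Cyp2b2 and Ugt1a1 had no probe set with a single symbol and were not analysed here by name, and 1 is not reported here. It took up to 5 called genes each way in the contrast of 641 with 64.1 mg/kg. As applied, these were limited to genes in which all 6 arrays at 641 mg/kg lay on the same side of the 64.1 mg/kg mean. Values of any other gene were chosen after they were seen.

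RNA quality was checked with the difference between the 3-prime and 5-prime control probe sets of Gapdh and actin, by exact permutation tests of 6 against 6 arrays. The smallest p these 924 splits allow is 0.002165. The limma step was tested on simulated data with the real means and spread over 31042 probe sets. For 641 mg/kg against vehicle it recovered 49.3% of the smallest simulated changes, which were under 1.5-fold, 94.0% of 1.5-fold changes and 98.5% of 2-fold changes, with 12 false calls among 173. For 64.1 mg/kg the shares were 53.7%, 98.5% and 97.0%, with 11 false calls among 177. The real data gave 13 calls at 64.1 mg/kg, so the adjusted threshold was laxer in the simulation. Its noise was also independent between probe sets. The shares therefore do not show how many real changes were detected at that dose.

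Alternatives covered the replicate number as a block, median centring, repeated quantile normalization, a filter on dim probe sets (a group mean of at least 6), and other variance models. They also covered array weights, a 1.5-fold minimum, a fit on the groups compared only, adjustment over the 5 doses together, the mean of a gene's probe sets, and leaving out each array. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.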

Results

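Transcripts were measured on 36 arrays of rat liver, 6 per group, after 5 daily oral doses of the brominated flame retardant HBCD at 641, 64.1, 6.41, 0.641 or 0.06 mg/kg or of corn oil vehicle. Values are log2 probe set levels, given as mean ± SD with n = 6 arrays per group. The design asks which liver transcripts differ from vehicle at each dose.

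At 641 mg/kg, the largest rises among the named genes were those of Abcc3, Gsta3 and Ces2c, and the largest falls those of Scd and Slc6a6. Abcc3, which encodes an exporter of conjugated compounds, rose 5.26-fold (95% CI 3.92 to 7.07; adjusted p = 9.92e-10), from 5.20 ± 0.37 to 7.59 ± 0.54. Gsta3, a glutathione transferase, rose 5.23-fold (3.90 to 7.00; adjusted p = 9.92e-10), from 7.52 ± 0.47 to 9.91 ± 0.35. Ces2c, a carboxylesterase, rose 4.41-fold (3.65 to 5.33; adjusted p = 1.88e-13). Scd, the desaturase that makes monounsaturated fatty acids, was 3.90-fold lower (2.41 to 6.31; adjusted p = 6.01e-04), at 7.97 ± 0.38 against 9.94 ± 1.09. Slc6a6, the taurine transporter, was 3.59-fold lower (2.66 to 4.84; adjusted p = 2.91e-07), at 7.55 ± 0.28 against 9.40 ± 0.41.

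The other leading rises at 641 mg/kg were those of the sulfotransferase Sult2a6 (3.46-fold), Cryl1 (2.50-fold), the retinaldehyde dehydrogenase Aldh1a1 (2.48-fold) and the monooxygenase Cyp3a23-3a1 (2.45-fold). Myc (2.30-fold), the aldehyde reductase Akr7a3 (2.30-fold) and cyclin Ccna2 (2.25-fold) followed, with adjusted p-values for these 7 genes between 1.52e-14 and 0.0322. The other leading falls were those of the fatty acid binding protein Fabp5 (1.82-fold lower), ornithine aminotransferase Oat (1.79-fold), the small GTPase gene Rhof (1.75-fold) and glycine methyltransferase Gnmt (1.71-fold). Coch (1.66-fold lower), Cd8a (1.58-fold), Klf9 (1.56-fold) and Plekhb1 (1.54-fold) also fell, with adjusted p-values for these 8 genes between 1.26e-06 and 0.0406. In each of these genes all 6 treated arrays lay on the same side of the vehicle mean, as the rule for naming them required. The mean levels of Ccna2 (4.48), Coch (4.28) and Cd8a (4.82) lay below every array median, so these probe sets may lie near the background. For Cd8a and Klf9, 1 of 3 probe sets was called, and for Cpt1a, Me1, Elovl5, Akr1d1 and Snx10, named in what follows, 1 of 2. A probe set listed under both Cyp2b1 and Cyp2b2, and assigned to neither, rose 4.01-fold (2.92 to 5.50; adjusted p = 1.98e-07).

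Among the lists fixed before the data were examined, targets of the xenobiotic receptors CAR and PXR rose at 641 mg/kg, with 13 of 17 measured members called higher, 14 adjusted over the list alone (camera adjusted p = 1.34e-43; adjusted p = 4.45e-07 with an estimated correlation). The called members included Ugt2b1 (2.13-fold), Abcb1a (1.89-fold) and Ephx1 (1.73-fold), and none was called lower. NRF2 targets, which serve glutathione and redox metabolism, rose in 10 of 18 measured members, 14 adjusted over the list alone (camera adjusted p = 5.02e-27; adjusted p = 3.76e-05 with an estimated correlation). Glutathione reductase Gsr rose 1.96-fold (1.73 to 2.23; adjusted p = 2.39e-09), and the subunits of glutamate-cysteine ligase, Gclc and Gclm, rose 1.45-fold and 1.57-fold. Ephx1 belongs to both lists, and Nqo1, at 2.08-fold, was not called (adjusted p = 0.119).

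Cell cycle genes were called higher in 9 of 27 members at 641 mg/kg, 18 adjusted over the list alone, and none was called lower (camera adjusted p = 3.13e-15). That list was not called with an estimated correlation (adjusted p = 0.139) and passed fry upward (adjusted p = 0.00979). Ccna2 is given above, Cdk1 rose 1.93-fold (1.35 to 2.77; adjusted p = 0.0465), and the replication helicase genes Mcm6 and Mcm4 rose 1.56-fold and 1.38-fold. Cyclin gene Ccnd1, at 0.834-fold, was not called (adjusted p = 0.589). Of the p53 targets, Mdm2 (1.30-fold) and Fas (1.42-fold, in 1 of 3 probe sets) were called higher among 15, the same 2 adjusted over the list alone, and the list was not called (camera adjusted p = 0.209).

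Members of the gluconeogenesis and glycolysis list fell in 2 of 12 cases at 641 mg/kg, 8 adjusted over the list alone, where 1 also rose (camera adjusted p = 4.63e-04; adjusted p = 0.111 with an estimated correlation). These were pyruvate carboxylase Pc (1.22-fold lower; adjusted p = 0.0417) and fructose bisphosphatase Fbp1 (1.16-fold lower; adjusted p = 0.0399), both part of glucose synthesis. In the list for the urea cycle and amino acid catabolism, 2 of 14 members fell, 7 adjusted over the list alone, where 1 rose (camera adjusted p = 3.78e-05; adjusted p = 0.195 with an estimated correlation). Argininosuccinate synthase Ass1 was 1.41-fold lower (adjusted p = 1.07e-04) and aspartate aminotransferase Got1 1.29-fold lower (adjusted p = 0.00773). The gluconeogenesis and urea cycle lists both passed fry downward (adjusted p = 0.0032 and 0.0105). Among 26 PPARalpha targets only Cpt1a, the carnitine transferase that admits fatty acids to mitochondria, was called, 1.49-fold lower (adjusted p = 5.58e-04), with 4 lower and 1 higher adjusted over the list alone. The PPARalpha list passed camera (adjusted p = 0.0191) and did not pass with an estimated correlation (adjusted p = 0.669), and it did not pass without vehicle replicate 1 (adjusted p = 0.160) or replicate 4 of 641 mg/kg (adjusted p = 0.0958). Cyp4a1, another member, stood at 0.793-fold (0.657 to 0.958; adjusted p = 0.281). The PPARalpha list did not pass fry (adjusted p = 0.257).

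Cholesterol synthesis genes stood higher as a list at 641 mg/kg (camera adjusted p = 4.63e-04; adjusted p = 0.706 with an estimated correlation), although none of 19 was called over all probe sets and 3 were higher adjusted over the list alone. Its member with the smallest p was Cyp51, at 1.24-fold (1.07 to 1.44; adjusted p = 0.149). The cholesterol synthesis list did not pass fry (adjusted p = 0.361). Its mean log2 shift of 0.158 lay below those at 0.641 (0.186) and 6.41 mg/kg (0.23). In fatty acid and triglyceride synthesis, Scd and Elovl5 (1.16-fold lower) fell and Me1 (1.52-fold) rose among 17 members, 3 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.639), and Fasn stood at 0.998-fold (0.815 to 1.22). Bile acid genes went both ways at 641 mg/kg, 3 higher and 1 lower of 19, with 3 each way adjusted over the list alone (camera adjusted p = 0.432; fry mixed adjusted p = 3.19e-17). The uptake transporter Slco1a4 rose 1.89-fold (adjusted p = 5.03e-08), the reductase Akr1d1 1.35-fold and Slco1a1 1.27-fold, and Slc27a5 was 1.27-fold lower. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, stood at 1.38-fold with a wide interval (0.737 to 2.59).

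Genes of thyroid hormone handling and response were called in 4 of 13 members upward and 2 downward at 641 mg/kg, 4 and 3 adjusted over the list alone (camera adjusted p = 0.477; fry adjusted p = 0.00778, mixed 1.81e-09). The list's median (-0.0789) and mean (0.0552) had opposite signs, and camera pointed up. Ugt2b1, Slco1a4, Me1 and Sult1b1 (1.19-fold) rose, Sult1a1 (1.20-fold lower) and Klf9 fell, and the deiodinase Dio1 stood at 0.915-fold (0.820 to 1.02; adjusted p = 0.572). Ugt2b1 is also in the CAR and PXR list, Slco1a4 in the bile acid list and Me1 in the NRF2 and fatty acid lists. Probe sets listed under the Ugt1a genes rose 1.37-fold (1.27 to 1.47) and 1.58-fold (1.44 to 1.75), with adjusted p-values of 2.91e-07 and 4.88e-08. Of 8 AhR targets 1 was called, Cyp1a2, which fell (1.38-fold lower; 95% CI 1.28 to 1.49; adjusted p = 6.42e-07), and Cyp1a1 stood at 1.16-fold (0.947 to 1.43; adjusted p = 0.623). The AhR list was not called (camera adjusted p = 0.773), with 1 member each way adjusted over the list alone, and its median (0.0102) and mean (0.0998) lay above 0 while camera pointed down. Male-predominant genes Cyp3a18 (1.99-fold), Slco1a1 and Cyp3a2 (1.13-fold) rose and Hao2 (1.27-fold lower) fell among 11, with the same numbers, 3 and 1, adjusted over the list alone (camera adjusted p = 0.184). Cyp3a18 and Cyp3a2 are also in the CAR and PXR list, and Slco1a1 in the bile acid list. Male-specific Cyp2c11 stood at 0.930-fold (0.860 to 1.01), and of 8 female-predominant genes 1, Sult2a2 (2.82 ± 0.13 against 2.50 ± 0.15, n = 6), was called higher, with 2 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.481). The mean level of Sult2a2 (2.55) lay below every array median, so that probe set may lie near the background.

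No member was called at 641 mg/kg in the lists for endoplasmic reticulum stress (21 genes, camera adjusted p = 0.147), heat shock (7 genes, 0.783), acute phase and inflammation (22 genes, 0.639), circadian clock (17 genes, 0.756) or hepatocyte secreted genes (12 genes, 0.0598). Of these, only the hepatocyte list had a member called when adjusted over the list alone, 1 lower. Their members with the smallest p were Creld2 (0.742-fold), Hspa1a (0.766-fold), Crp (1.11-fold), Npas2 (0.790-fold) and Serpina1 (0.931-fold), with adjusted p-values from 0.116 to 0.337. Serpina1 was called lower (adjusted p = 0.0267) when each gene was tested once, as the mean of its probe sets. The heat shock median (-0.0174) and mean (-0.0315) lay below 0 while camera pointed up, and the acute phase mean of -0.00358 turned to 0.00631 with each array centred on its median.

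Markers of other cell types did not pass as lists at 641 mg/kg, with camera adjusted p-values of 0.425 for cholangiocytes, 0.307 for macrophages, 0.632 for stellate cells and fibroblasts, and 0.0977 for endothelium. The values were 0.456 for T and NK lymphocytes, 0.806 for B lymphocytes, 0.110 for neutrophils, 0.602 for erythroid cells and 0.590 for exocrine pancreas. Cd8a was the only called member among them, and the only one called when adjusted over each list alone. The members with the smallest p stood at 1.17-fold for Epcam, 0.900-fold for Cd163, 0.824-fold for Pdgfrb, 0.863-fold for Fcgr2b, 0.959-fold for Cd22, 0.862-fold for Csf3r, 0.901-fold for Alas2 and 0.807-fold for Cela1.

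Over all probe sets at 641 mg/kg, 352 were higher and 159 lower of 31042 tested. Of these, 248 and 105 were the probe sets that stood for a gene symbol. Changes of at least 1.5-fold numbered 75 upward and 21 downward, and of at least 2-fold 18 and 3. The total of 511 was 335 without replicate 2 of the 641 mg/kg group, 327 when only the 2 groups entered the fit, and 225 when the 5 doses were adjusted together. Me1, Elovl5, Sult2a2, Mdm2, Pc, Fbp1 and Got1 were not called in the fit of the 2 groups, Cd8a, Klf9, Elovl5 and Fas not with the mean of their probe sets, and Pc and Fbp1 not with arrays centred on their medians. With the replicate number as a block, Coch and Fbp1 were not called.

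**Figure D1:**
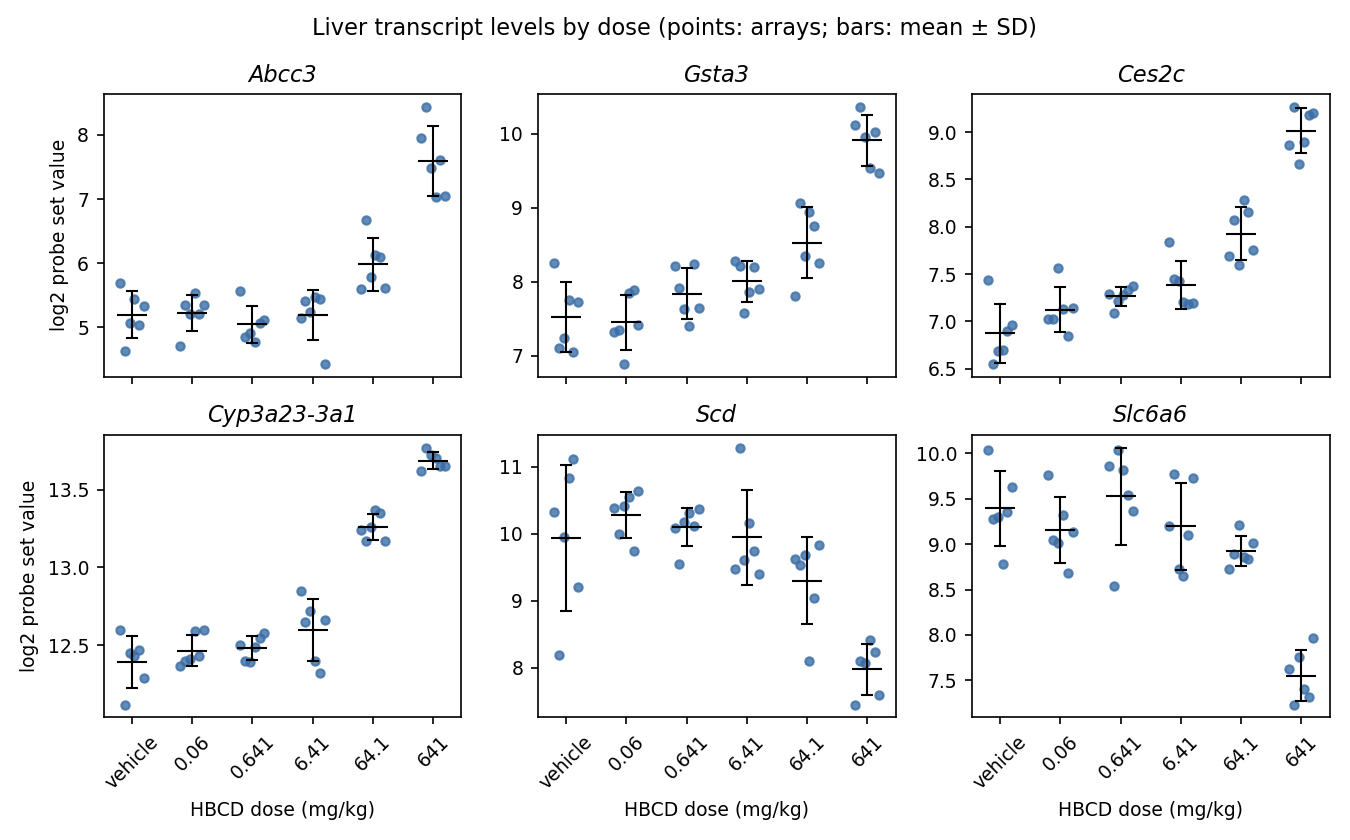
Levels of 6 transcripts by dose; the vertical axes are log2 probe set values (scales differ between panels), the horizontal axes the dose in mg/kg, each point 1 array, and the bars mean ± SD (n = 6). Abcc3, Gsta3, Ces2c and Cyp3a23-3a1 were 5.26, 5.23, 4.41 and 2.45 times the vehicle level at 641 mg/kg, and Scd and Slc6a6 were 3.90-fold and 3.59-fold lower.

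At 64.1 mg/kg, all calls were rises, and 7 of the 10 named genes belonged to the list of CAR and PXR targets. Ces2c rose 2.07-fold (95% CI 1.72 to 2.51; adjusted p = 3.45e-05), from 6.87 ± 0.32 to 7.93 ± 0.28. Cyp3a23-3a1 rose 1.82-fold (1.64 to 2.02; adjusted p = 2.58e-09), from 12.39 ± 0.17 to 13.26 ± 0.088. The glucuronosyltransferase Ugt2b1 rose 1.70-fold (1.49 to 1.93; adjusted p = 1.34e-05) and Aldh1a1 1.66-fold (1.42 to 1.95; adjusted p = 0.00116). Cyp3a18 (1.47-fold), the steroid dehydrogenase Hsd17b2 (1.46-fold), Ugt2a1 (1.40-fold), the epoxide hydrolase Ephx1 (1.36-fold), Mgst2 (1.30-fold) and Cyp2c6v1 (1.16-fold) completed the genes called by the probe set that stood for them, with adjusted p-values from 0.002 to 0.0292. All 6 treated arrays lay above the vehicle mean for each of the 10 genes.

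The probe set listed under Cyp2b1 and Cyp2b2 rose 2.63-fold at 64.1 mg/kg (1.91 to 3.60; adjusted p = 0.00217), and 1 of the Ugt1a probe sets rose 1.27-fold (adjusted p = 0.0336). CAR and PXR targets rose in 7 of 17 members, 12 adjusted over the list alone (camera adjusted p = 1.49e-32; adjusted p = 4.57e-06 with an estimated correlation). Abcc3 stood at 1.72-fold (1.28 to 2.31; adjusted p = 0.390) and was not called. Of the NRF2 targets 1 of 18, Ephx1, was called, with 5 higher and 1 lower adjusted over the list alone (camera adjusted p = 1.69e-05; adjusted p = 0.139 with an estimated correlation). Macrophage markers stood lower in the same group (camera adjusted p = 1.11e-09; adjusted p = 0.195 with an estimated correlation), with none of 10 called over all probe sets and 9 lower adjusted over the list alone. Their mean shift was -0.43 on the log2 scale, and neutrophil markers shifted by -0.28, with 3 of 4 lower adjusted over the list alone (camera adjusted p = 0.00308; adjusted p = 0.141 with an estimated correlation). Male-predominant (0.00451), cholesterol synthesis (0.0119) and cell cycle genes (0.0191) also passed camera upward, and none passed with an estimated correlation (adjusted p = 0.397, 0.731 and 0.731). Cyp3a18, the only called member of the male-predominant list at this dose, also belongs to the CAR and PXR list. The thyroid hormone list passed fry upward (adjusted p = 0.0103) and not camera (adjusted p = 0.114), and its only called member, Ugt2b1, is also in the CAR and PXR list.

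The calls at 64.1 mg/kg numbered 13 probe sets higher and none lower, against 1843 of 31042 at an unadjusted p under 0.05, where 1552.1 are expected by chance. The count was 28 among probe sets with a group mean of at least 6, 24 with a variance trend and robust moderation, and 20 when the 5 doses were adjusted together. It was 8 without vehicle replicate 3 or without replicate 4 of 64.1 mg/kg, 5 when only the 2 groups entered the fit, where Aldh1a1, Hsd17b2, Ugt2a1, Ephx1, Mgst2 and Cyp2c6v1 were not called, and 3 without the replicates 2, 3 and 4 of 64.1 mg/kg, in which the macrophage markers stood lowest. Cyp2c6v1 was also not called with the replicate number as a block.

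All 13 probe sets called at 64.1 mg/kg were also higher at 641 mg/kg, each with a larger fold. Ces2c went from 2.07-fold to 4.41-fold, Ugt2b1 from 1.70-fold to 2.13-fold and Ephx1 from 1.36-fold to 1.73-fold. Independent lists would share 0.147 probe sets. Both contrasts use the same vehicle arrays. Simulated unchanged groups against shared vehicle arrays gave a mean overlap of 0.05 and at most 3 in 100 simulations. Neither dose had an effect in these simulations, so they cannot show what shared arrays add beside 511 calls at 641 mg/kg. With the vehicle arrays split into separate sets of 3, the overlap had a median of 5 and a range of 2 to 14 over 20 splits, in which 2 to 17 probe sets were called at 64.1 mg/kg and 120 to 293 at 641 mg/kg. The log2 fold changes at these doses correlated across probe sets at r = 0.539, against 0.492 in the simulation and 0.158 on average with split vehicle arrays, where probe sets are not independent replicates. Their covariance was 0.00791, against 0.00431 simulated. The doses 0.06, 0.641 and 6.41 mg/kg, which had no calls, also lay above the simulation. Their covariances with 641 mg/kg were 0.00584, 0.00628 and 0.00526, against 0.00432, 0.00428 and 0.00425. The simulation used deviations from group means, which spread less than the arrays, so part of each excess may come from that.

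Between the highest doses, Abcc3, Gsta3 and Ces2c stood higher and Slc6a6 lower at 641 than at 64.1 mg/kg. Abcc3 differed 3.06-fold (95% CI 2.28 to 4.11; adjusted p = 5.09e-05), Gsta3 2.61-fold (1.95 to 3.50; adjusted p = 4.10e-04), and Ces2c 2.13-fold (1.76 to 2.57; adjusted p = 2.40e-05). Snx10 (2.01-fold; adjusted p = 0.0425) and Cryl1 (1.84-fold; adjusted p = 2.40e-05) were also higher. For each of these genes all 6 arrays at 641 mg/kg lay above the 64.1 mg/kg mean, as the rule for naming them required. Lower at 641 than at 64.1 mg/kg were Slc6a6 (2.59-fold; 1.92 to 3.48; adjusted p = 6.19e-04), the hydrolase Abhd2 (1.46-fold), Plekhb1 (1.37-fold), Gnmt (1.35-fold) and the polyamine acetyltransferase Sat1 (1.27-fold), each in 6 of 6 arrays, again by the rule. Scd differed 2.51-fold in the lower direction without passing (adjusted p = 0.113), and the Cyp2b probe set 1.53-fold upward (adjusted p = 0.380). In all, 59 probe sets were higher and 16 lower, of which 66 were also called the same way at 641 mg/kg against vehicle, and 9 of the 13 calls at 64.1 mg/kg were among them. The total of 75 was 32 without replicate 2 and 40 without replicate 5 of 641 mg/kg, and 43 and 39 without replicates 3 and 6 of 64.1 mg/kg. It was 35 when only the 2 groups entered the fit, and Plekhb1 and Sat1 were not called with arrays centred on their medians, nor Snx10 with the mean of its probe sets. With the replicate number as a block, Snx10 and Gnmt were not called.

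At 0.06, 0.641 and 6.41 mg/kg no gene was called. Cyp3a23-3a1 stood at 1.05-fold (0.949 to 1.17), 1.07-fold (0.962 to 1.18) and 1.15-fold (1.04 to 1.28), and Abcc3 at 1.02-fold, 0.900-fold and 0.993-fold. The probe set listed under Cyp2b1 and Cyp2b2 stood at 1.29-fold (0.941 to 1.77), 1.36-fold (0.993 to 1.87) and 1.78-fold (1.30 to 2.44). Cyp7a1 stood at 1.67-fold (0.890 to 3.13), 1.65-fold (0.883 to 3.10) and 1.255-fold (0.669 to 2.35). Cyp1a1 (1.01-fold to 1.16-fold), Cyp1a2 (0.980-fold to 1.04-fold), Cyp4a1 (1.02-fold to 1.09-fold), Fasn (0.993-fold to 1.11-fold), Dio1 (0.992-fold to 1.04-fold) and Cyp2c11 (1.01-fold to 1.05-fold) stood close to vehicle, with adjusted p-values of 0.999 or 1 for these genes.

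With limma, 0 of 31042 probe sets were called at each of these doses, and 1293, 1477 and 1282 had an unadjusted p under 0.05, where 1552.1 are expected by chance. Unmoderated contrasts also gave 0 at each dose, and adjustment over the 5 doses together gave 0, 2 and 1. Lists that passed camera upward at these doses were cholesterol synthesis (adjusted p = 0.00397, 5.77e-10 and 2.69e-12), fatty acid synthesis (4.16e-05, 1.73e-05 and 0.00223) and CAR and PXR targets at 0.641 (5.70e-04) and 6.41 mg/kg (4.63e-06). None passed with an estimated correlation, where the adjusted p was 0.724, 0.295 and 0.227 for cholesterol synthesis, 0.139, 0.132 and 0.274 for fatty acid synthesis, and 0.227 and 0.111 for CAR and PXR targets. Adjusted over the list alone, 5 of 17 CAR and PXR targets were higher at 6.41 mg/kg, and of 17 fatty acid synthesis genes 2 were higher at 0.06 and 1 at 0.641 mg/kg, while no cholesterol synthesis gene was called in this way. All dose contrasts share the vehicle arrays, so passing at several doses is not independent evidence. From 0.06 to 641 mg/kg, mean log2 shifts were 0.0875, 0.186, 0.23, 0.0828 and 0.158 for cholesterol synthesis. For fatty acid synthesis they were 0.164, 0.168, 0.122, 0.0539 and -0.087, so neither list rose steadily with dose. The thyroid hormone list passed camera (adjusted p = 0.0117) and fry (adjusted p = 0.0103) upward at 6.41 mg/kg, with 1 of 13 higher adjusted over the list alone, and not camera with an estimated correlation (adjusted p = 0.082). P53 targets at 0.06 mg/kg (0.00582; adjusted p = 0.082 with an estimated correlation) and NRF2 targets at 0.641 mg/kg (0.028; adjusted p = 0.586 with an estimated correlation) also passed camera upward. The cell cycle list also passed camera upward at 0.06, 0.641 and 6.41 mg/kg (0.00137, 3.78e-05 and 0.00323), with none of 27 members called and none higher adjusted over the list alone, and did not pass with an estimated correlation (adjusted p = 0.706, 0.586 and 0.706). Of the cell type markers, those of neutrophils stood lower at 0.06 (camera adjusted p = 0.0173; adjusted p = 0.246 with an estimated correlation) and 0.641 mg/kg (0.0224; 0.274 with an estimated correlation). Endothelial markers stood lower at the same doses (0.0412 and 0.0456; 0.586 at both with an estimated correlation), and macrophage markers at 0.641 mg/kg (0.0199; 0.724 with an estimated correlation).

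**Figure D2:**
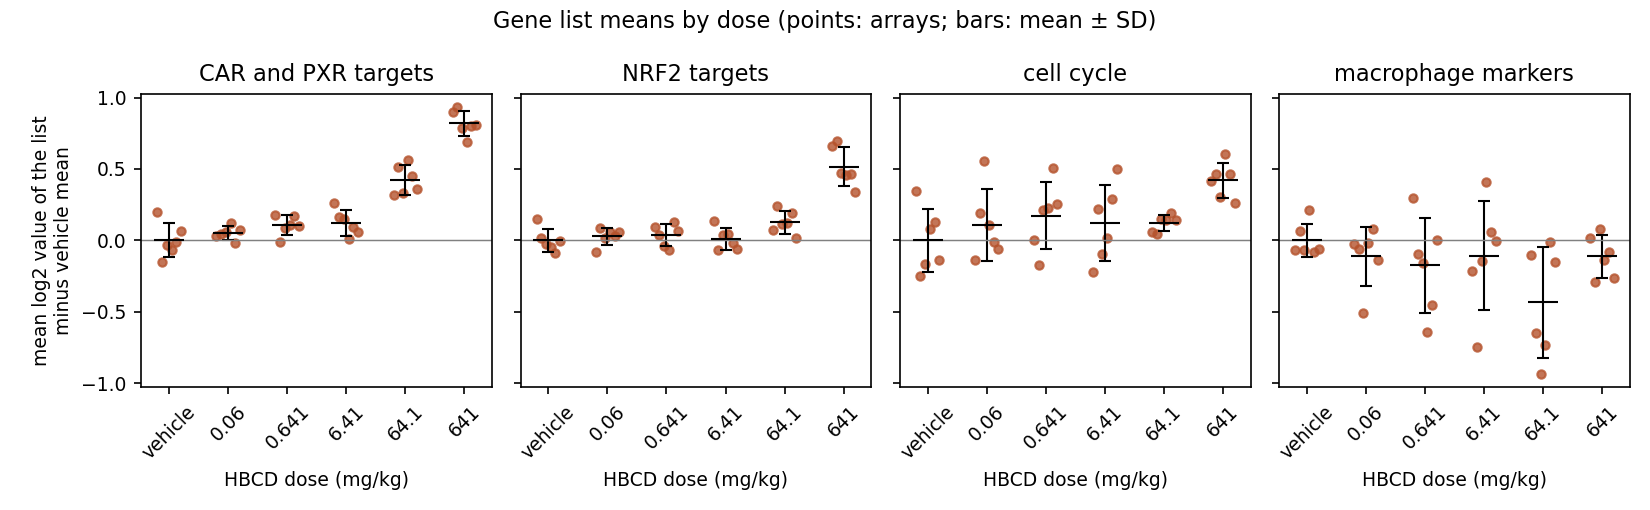
Mean level of 4 gene lists by dose; the vertical axis is the mean log2 value over a list minus the vehicle mean, the horizontal axes the dose in mg/kg, each point 1 array, and the bars mean ± SD (n = 6). CAR and PXR targets had 7 of 17 members called higher at 64.1 mg/kg and 13 at 641 mg/kg, and the macrophage markers spread from -0.937 to -0.0134 at 64.1 mg/kg.

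Across the whole dose series, the linear contrast over dose ranks called 280 probe sets upward and 138 downward. Of these, 216 and 91 were the probe sets that stood for a gene symbol. The total of 418 was 653 among probe sets with a group mean of at least 6. Of the 418, 341 were also called the same way at 641 mg/kg and 77 at no single dose. The contrast weights vehicle and 641 mg/kg most, so a change at 641 mg/kg alone can pass. A pass therefore does not show a response graded over all doses. The moderated F test over the 5 dose contrasts called 240 probe sets, 374 among those with a group mean of at least 6, and 154 without replicate 2 of 641 mg/kg.

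The control probe sets gave no sign of a difference in RNA quality between groups. The 3-prime minus 5-prime difference of Gapdh was 0.0040 ± 0.039 in vehicle and -0.023 ± 0.026 at 641 mg/kg (n = 6; exact permutation p = 0.180), and that of actin was 1.17 ± 0.14 and 1.14 ± 0.063 (exact permutation p = 0.597). The smallest adjusted p over 15 such exact tests, array medians included, was 0.885, and limma called 0 of 57 control probe sets at any dose.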

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

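Each named gene and each quality measure was examined for 1 array far from the other 5 of its group, by the gap to its nearest neighbour relative to the range. Of 213 sets of 6 values, 11 met the limit, where chance gives about 1 in 20 sets, or 10.7. They are given as values, with no explanation.

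Among genes of xenobiotic and lipid metabolism, Abcc3 stood at 4.43 in replicate 6 of 6.41 mg/kg, below the other arrays (5.14 to 5.47). Cyp1a1 stood at 4.97 in replicate 1 of 641 mg/kg, above the others (4.52 to 4.68). Cyp7a1 stood at 9.70 in replicate 4 of 0.641 mg/kg, below the others (10.91 to 11.63). Fasn stood at 9.18 in replicate 5 of 6.41 mg/kg (others 9.72 to 10.01), and Pc at 9.12 in vehicle replicate 4 (others 9.38 to 9.49).

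Mdm2, called at 641 mg/kg, stood at 8.27 in replicate 2 of that group, above the others (7.56 to 7.79). Coch, also called there, stood at 5.16 in vehicle replicate 2 (5.155 before rounding), above the others (4.30 to 4.62). Cd22 stood at 5.78 in vehicle replicate 4 (others 5.57 to 5.64) and Pdgfrb at 5.63 in vehicle replicate 5 (others 5.15 to 5.30). The Gapdh 3-prime minus 5-prime difference was 0.189 in replicate 2 of 0.641 mg/kg (others -0.0994 to 0.0042). That of actin was 1.44 in replicate 2 of 0.06 mg/kg (1.435 before rounding; others 1.08 to 1.19).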

How the results depend on the processing

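The fit without replicates 2, 3 and 4 of 64.1 mg/kg and the leave-one-out tests of single lists were chosen after the data had been seen. The counts named here are those at 64.1 mg/kg, at 641 mg/kg, between 641 and 64.1 mg/kg, at both, over the dose ranks and in the F test (13, 511, 75, 13, 418 and 240). No count moved by over 1.5 times with median centring, repeated quantile normalization, unmoderated variances or array weights. Restricting the test to probe sets with a group mean of at least 6 left 11258 and gave 28 at 64.1 mg/kg, 27 at both doses, 653 over ranks and 374 in the F test, from fewer tests. A variance trend with robust moderation gave 24 at 64.1 mg/kg and 24 at both, and the cause was not tested. The 1.5-fold minimum left 6, 96, 20, 6 and, over ranks (per dose step), 1, by construction. With only the groups compared in the fit, which has fewer arrays, the counts were 5, 327, 35 and 5. Adjusted over the 5 doses together, they were 2 at 0.641, 1 at 6.41, 20 at 64.1 and 225 at 641 mg/kg. Without replicates 2, 3 and 4, 64.1 mg/kg had 3 calls, from fewer arrays.

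Leaving out each array gave 8 to 18 calls at 64.1 mg/kg and at both doses (8 without vehicle replicate 3 or 64.1 mg/kg replicate 4), 335 to 507 at 641 mg/kg, and 154 to 258 in the F test (335 and 154 without 641 mg/kg replicate 2). It gave 32 to 95 between the highest doses (32 and 40 without 641 mg/kg replicates 2 and 5, 43 and 39 without 64.1 mg/kg replicates 3 and 6) and 316 to 428 over ranks. With an estimated correlation, 3 of 140 list tests passed in place of 33, where the other settings gave 31 to 37, and the cause was not tested. Those lost included the macrophage list at 64.1 mg/kg (adjusted p = 0.195), each list that had passed at the 3 lower doses and, at 641 mg/kg, the lists for cell cycle (0.139), cholesterol synthesis (0.706), gluconeogenesis (0.111), urea cycle (0.195) and PPARalpha (0.669). Of these lists at 641 mg/kg, cell cycle, gluconeogenesis and urea cycle passed fry (adjusted p = 0.00979, 0.0032 and 0.0105). Cholesterol synthesis and PPARalpha did not pass fry (adjusted p = 0.361 and 0.257). The PPARalpha list ranged from 0.00344 to 0.160 over leave-one-out (0.160 without vehicle replicate 1, 0.0958 without 641 mg/kg replicate 4). CAR and PXR targets at both doses and NRF2 targets at 641 mg/kg passed in each of these settings. Of 454 comparisons of single named genes, 426 kept their direction and side of the threshold, 27 were no longer called, 1 was newly called (Serpina1 at 641 mg/kg with 1 test per gene, adjusted p = 0.0267, from fewer tests) and 0 reversed. The lost calls were those of Aldh1a1, Hsd17b2, Ugt2a1, Ephx1, Mgst2 and Cyp2c6v1 at 64.1 mg/kg and Me1, Elovl5, Sult2a2, Mdm2, Pc, Fbp1 and Got1 at 641 mg/kg with only the groups compared (smallest adjusted p 0.0508, from fewer arrays). With the mean of a gene's probe sets they were Cd8a, Klf9, Elovl5 and Fas at 641 mg/kg and Snx10 between the highest doses (0.0685 to 0.287). With median centring they were Pc and Fbp1 at 641 mg/kg and Plekhb1 and Sat1 between the highest doses (0.0508 to 0.070).

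With the replicate number as a block, 12 probe sets were called at 64.1 mg/kg, 500 at 641 mg/kg, 64 between them, 12 at both, 380 over ranks and 231 in the F test, and Cyp2c6v1 at 64.1 mg/kg, Coch and Fbp1 at 641 mg/kg, and Snx10 and Gnmt between these doses were not called (adjusted p from 0.0517 to 0.074). Same-numbered arrays of different groups shared little: their deviations correlated at 0.0179 on average (-0.252 to 0.321; 14 of 90 pairs above 0.1), and 6 of 36 arrays correlated best with their own number. Dim probe sets lie near the background, where small changes are hard to see.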

Other observations

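Gene families picked by the start of the symbol were also counted at 641 mg/kg. They were chosen after the called genes had been seen and in part repeat the lists, so their p-values are no independent support. Fisher's exact test with adjustment over 22 tests also treats genes as independent. Glutathione transferase (Gst) genes were called higher in 7 of 20 cases and none lower (adjusted p = 6.35e-07), led by Gsta3 and Gstt3 (2.10-fold). Aldo-keto reductase (Akr) genes were called higher in 5 of 15 cases (adjusted p = 2.96e-05), among them Akr7a3 (2.30-fold) and Akr1d1 (1.35-fold). Glucuronosyltransferases with a probe set of their own were called higher in 4 of 9 cases (adjusted p = 5.85e-05), including Ugt2b1 (2.13-fold) and Ugt2a1 (1.97-fold). Replication licensing (Mcm) genes were called higher in 3 of 10 cases (adjusted p = 0.00253), all of them called members of the cell cycle list. Sulfotransferase (Sult) genes were called higher in 3 of 14 cases (adjusted p = 0.00607), with 1 lower. The 3 include Sult2a2, whose probe set may lie near the background. Families that did not pass were the transporters Abcc (1 of 9 higher, adjusted p = 0.248) and Slco (2 of 13 higher and 1 lower, adjusted p = 0.0573) and Mgst (1 of 3 higher, adjusted p = 0.126).

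Proteasome (Psm) genes were called higher in 8 of 46 cases at 641 mg/kg and none lower (adjusted p = 1.24e-05). The rises were small, from 1.14-fold for Psma1 and Psmd8 to 1.29-fold for Psmd5, with Psmb3 at 1.21-fold and Psme1 at 1.18-fold. Of 34 ribosomal protein genes of the large subunit (Rpl) 0 were called in either direction. Cytochrome P450 (Cyp) genes were called in 5 of 58 cases upward (adjusted p = 0.0105) and 2 downward, Cyp1a2 and Cyp2b3, which did not pass as a group. All 5 called upward were called members of the CAR and PXR list.

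In the weighing of the patterns that follow, the tests against marker lists, single arrays, permuted arrays and low vehicle arrays were chosen after the results were seen. The splits, the RNA quality test and the dose score tests were written first.

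The cell cycle list stood 0.42 higher on the log2 scale at 641 mg/kg (95% CI 0.176 to 0.664 over arrays), in 6 of 6 arrays above the vehicle mean, and 0.108, 0.173, 0.119 and 0.121 higher at 0.06, 0.641, 6.41 and 64.1 mg/kg. The 641 mg/kg arrays stood 0.289 (0.0966 to 0.482; exact permutation p = 0.0027) above the mean of these 4 doses, so low vehicle arrays may account for part of the shift and not for all of it. With both 3-prime minus 5-prime differences as covariates the shift was 0.402 (0.153 to 0.652). These measures hardly differed between 641 mg/kg and vehicle (-0.0266 for Gapdh, -0.0358 for actin), so the covariates could hardly have removed the shift. The values argue against RNA quality only as far as these 2 measures capture it. Leaving out any 1 array left a shift of at least 0.37. The shift exceeded that of each of the 8 marker lists of non-hepatocyte liver and blood cells, least surely that of macrophages (difference 0.531; 0.0693 to 0.993), which argues against more such cells dividing at their usual rate. An exact permutation test of the array means gave an adjusted p of 0.0325 over 5 doses (0.00649 unadjusted). Adjusted over all 140 list tests, camera with an estimated correlation gave 0.139 and fry gave 0.00979. The list was singled out among 28, and neither the adjustment over 5 doses nor the permutation p of 0.0027 covers this choice. The tests adjusted over all lists differed, so chance is not excluded. A larger share of cells in the cell cycle at 641 mg/kg stays a candidate explanation, as a hypothesis that transcript levels alone do not test.

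The list of macrophage markers, none of them in another list, stood at -0.432 at 64.1 mg/kg, led by Clec4f (-0.61) and Cd5l (-0.61, mean level 9.13), with Lyz2 at -0.054, and at -0.112 at 641 mg/kg (641 against 64.1 mg/kg, exact permutation p = 0.108). The arrays of 64.1 mg/kg stood at -0.104, -0.652, -0.937, -0.735, -0.0134 and -0.152, with the weakest mean shift without 1 array at -0.331. It lay below the mean of the endothelial, stellate cell and cholangiocyte lists by -0.387 (95% CI -0.736 to -0.0387), which argues against a lower share of all non-hepatocyte cells alike, while the neutrophil (-0.281), erythroid (-0.154), B (-0.147) and T and NK (-0.140) lists also lay below 0, so that a lower share of blood and immune cells stays open. The exact permutation p, 0.0238, became 0.119 when adjusted over the 5 doses, so chance stays open. Fewer macrophages in the pieces sampled, or lower transcript levels in them, may also account for it, and these were not tested.

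A score over the 75 probe sets called between 641 and 64.1 mg/kg (those higher minus those lower), a contrast without the vehicle or lower-dose means, asks whether that response was present below 64.1 mg/kg. Above vehicle it stood at 0.0448 (95% CI -0.0234 to 0.113) at 0.06, 0.0625 (-0.0057 to 0.131) at 0.641 and 0.0765 (0.00831 to 0.145) at 6.41 mg/kg, against 0.188 at 64.1 and 0.697 at 641 mg/kg. The adjusted exact permutation p was 0.165, 0.0877 and 0.0877 (0.165, 0.0584 and 0.0325 unadjusted), with 5, 5 and 6 of 6 arrays above the vehicle mean. Without vehicle, the slope over the 3 lower doses was 0.0159 per dose step (-0.0138 to 0.0456; permutation p = 0.284). A small response at 6.41 mg/kg and vehicle arrays that happened to lie low cannot be told apart with 6 arrays per group.

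Other assignments of the same arrays to groups were drawn, 100 per comparison with the real one included. A count as large as the real one came up in 1 of 100, the real one, for 641 mg/kg (511 probe sets, highest other 42), 64.1 mg/kg (13, highest other 8), 641 against 64.1 mg/kg (75, highest other 5), the F test (240, highest other 4) and the dose ranks (418, highest other 1). For these, a chance assignment of separate samples can be excluded at that level. The labels do not state that each array came from a separate rat. If replicates were technical, the splits could not exclude chance differences between rats. For 0.06, 0.641 and 6.41 mg/kg, where the real count was 0, all 100 splits reached it, with highest others of 3, 43 and 1. The 1 split with 43 at 0.641 mg/kg may point to a structure of these samples, whose nature was not tested. For gene lists at the preset correlation chance cannot be excluded, as 7 lists at 641 mg/kg were reached in 15 of 100 splits (highest other 9) and 7 at 64.1 mg/kg in 12 of 100 (highest other 10). With an estimated correlation, the count of 2 lists at 641 mg/kg was reached in 2 of 100 splits, the real one included, and the other split gave 3. Such a count was rare among the splits, but chance is not excluded, and the count does not bear on which lists passed. The count of 1 list at 64.1 mg/kg was reached in 6 of 100 (highest other 1), so chance is not excluded there either.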
